A study of Mus musculus with 14 samples.

How the data were processed

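The deposited table holds signal intensity for 12488 probe sets on 14 MG-U74Av2 arrays, 1 array per transplanted mouse heart, on a linear scale. The labels give the group, the day after transplantation and the replicate number of each heart. The software that made the signals and the scaling the authors applied are not given in the sources used here. From the deposited values themselves, the mean intensity without the lowest and highest 2% was 100.06 to 100.07 on every array, no value was negative, the highest was 10828.7, and the authors' values were not centred per gene. Scanner files were not used here. Whether replicate hearts come from separate operations or litters is not stated, and each array was taken as 1 independent heart.

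Because the trimmed means lay within 1.1-fold of each other, the deposited intensity was used without further scaling. Signals under a floor of 11, the 25th percentile of all values, were set to the floor, and log2 was taken. Left out were 66 control probe sets. The 10395 probe sets above the floor on at least 3 of the 14 arrays were tested, 83.7% of the rest of the table, and they represent 7366 genes. Gene symbols came from the platform annotation, updated by gene ID through a RefSeq table. Of the probe sets, 10833 had 1 gene, 396 several and 1193 none, and no gene was named from a probe set with several. For 10817 of the 10833 the gene ID was in the RefSeq table. No coordinates are given, as no genome was used.

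All 5 groups entered 1 fit with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend), with 9 residual and 4.45 prior degrees of freedom. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the probe sets of a comparison, with a threshold of 0.05. There were 6 comparisons of 2 groups and 1 interaction. A change is called higher or lower only past that threshold. Differences are log2 of the first group minus the second, with their standard errors. Where every array of a group lay at or under the floor, the fold is taken against the floor and given as "at least". For genes with several probe sets, the brightest over all arrays stands for the gene. Genes with probe sets called in opposite directions were Atp5d, Lef1, Sh3bgr and Ttc39b in rejecting allografts against isografts, and Pdxdc1 in tolerizing allografts against isografts at both days.

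The test was tried on simulated data with 100 probe sets changed by a log2 of 1 and 100 by a log2 of 2 among 10395. It called 51% and 93% of them for rejecting against isograft hearts at day 7, 56% and 91% for tolerizing against isograft hearts at day 7, and 50% and 91% for rejecting against tolerizing hearts. It called 30% and 87% for the comparison at day 70, 44% and 84% for tolerizing hearts over time and 39% and 89% for isografts over time. False calls were 10, 8, 9, 8, 4 and 6. The changed probe sets were drawn only from those with a mean well above the floor. The shares called therefore do not cover dim probe sets. The simulated noise was independent between probe sets, with the same spread in all groups and no difference between runs. The shares and false calls hold for that setting only.

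Before the data were examined, the design, the gene lists, the alternatives and the rule for naming genes were fixed. The rule takes, per comparison, the 6 largest rises and falls among called genes measured on all arrays, the 4 brightest called genes with 1 group at the floor, up to 4 genes per list with the smallest p, and H2-Ea. The rule names 218 called genes, counted per comparison, none of them in the comparisons over time or the interaction, and the text prints the differences of 53. Those 53 were picked with their values and their stability known, so they keep their calls more often than the rest, as the closing part on processing shows. Of 30 gene lists, 29 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They hold 822 entries, of which 630 were tested, and 27 genes are in more than 1 list. Each list call was set beside camera with a correlation estimated per list, which asks more of a list whose genes vary together, and beside limma's fry. Intervals of list means are 95% intervals from the 14 arrays.

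The arrays carry 2 accession runs, and the 18S and BioC controls separate them completely, while the ranges of CreX overlap. The cause of the runs is not given in the sources used here. Counts of comparisons with at least 1 call are given with the run as a block and for the second run alone. The median in either run is printed for some lists only. The first run has 1 array per group and allows no test. Donor strain differs in every comparison of an allograft with an isograft, and its share cannot be separated from that of the immune response.

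Alternatives were quantile and median scaling, other floors, a pseudocount, other filters, no intensity trend, array weights, a block for the replicate number, the groups of a comparison alone, a 2-fold minimum, and leaving out each array in turn. The second run alone, the log2 ratio of 3' to 5' beta-actin signal as a covariate, and the run as a block for list shifts and for the overlap, were added after the data were seen. Explanations of patterns were tested against predictions written before the test values were computed, but after a first look at the counts and the top genes of each comparison. That look also showed the signals of H2-Ea and of H2-Eb1, which is 1 of the 6 class II genes in a prediction. In 3 of these predictions a median and its standard error can be read as a median of gene differences or as a difference of array medians. For lymphoid tissue these readings gave different verdicts, and a first version of the test, which mixed them, had ruled it out. Both are now printed for all 3. The standard errors of these tests pool the spread of all 14 arrays, including isografts, of which 4 of 5 are under the floor for H2-Ea, so those from the arrays compared alone were added after the results were seen. A verdict was taken only where both readings and both standard errors led to it. For the dilution of matrix genes, a condition was added after the value was seen: a value within 2 standard errors counts for the explanation only where 2 standard errors are smaller than the shift to be explained. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.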

Results

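Gene expression was measured in 14 transplanted mouse hearts, each on 1 MG-U74Av2 oligonucleotide array. Isografts were C57BL/6 hearts placed in C57BL/6 recipients. Allografts were Balb/c hearts placed in C57BL/6 recipients, either untreated and rejecting or tolerizing under antibodies against CD80 and CD86, which block the costimulation of T cells. The groups were isografts at day 7 (n = 3), rejecting allografts at day 7 (n = 3), tolerizing allografts at day 7 (n = 3), isografts at day 70 (n = 2) and tolerizing allografts at day 70 (n = 3). Every array had a trimmed mean signal of 100.06 to 100.07, a median signal of 38.2 to 45.65, and 71.97% to 78.8% of probe sets above the floor signal of 11. Correlations across probe sets lay between 0.872 and 0.959 within groups and between 0.761 and 0.955 between groups. The arrays fall into 2 submission runs, 5 arrays in the first and 9 in the second, and each run holds all 5 groups. The 3' signal of the 18S control separated the runs completely, at 30.3 to 83.4 in the first and 120.4 to 254.6 in the second. The ratio of 3' to 5' signal of beta-actin, a sign of RNA quality, differed between groups. It was 1.52 to 1.98 in isografts at day 7, 1.26 to 1.61 in rejecting and 1.09 to 1.37 in tolerizing allografts at day 7, 1.75 to 1.76 in isografts at day 70 and 1.24 to 1.69 in tolerizing allografts at day 70. The ratio of Gapdh was 0.818 to 1.13. The number of arrays limits the precision of every value.

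H2-Ea served as a check of the donor labels, because C57BL/6 mice carry a null allele of this gene. Its signal was 2.5 to 8.1 in the 3 isografts at day 7 and 5.6 and 12.3 in the 2 at day 70. It was 408.5, 442.1 and 552 in the 3 tolerizing allografts at day 7, and 489, 537.8 and 446 in those at day 70. The rejecting allografts gave 48.1, 50.4 and 217.3. Each of the 9 allografts was above each of the 5 isografts, so no array went against its strain label.

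The comparison of rejecting allografts with isografts at day 7 asks what an untreated allograft expresses beyond the effects of surgery. Recipients were of 1 strain, but donor strain differs between these groups and is part of every difference. Of 10395 probe sets tested, 1842 changed, 888 higher and 954 lower. Without 1 of the arrays in turn the count was 1307 to 2168. It was 2088 with the submission run as a block, 1665 in the second run alone, 1153 in a fit of these 2 groups alone and 1453 with the beta-actin ratio as a covariate. The first run has 1 array per group and gave the same sign for 1824 of the 1842, a number that is partly circular because those arrays helped to make the calls.

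**Figure D1:**
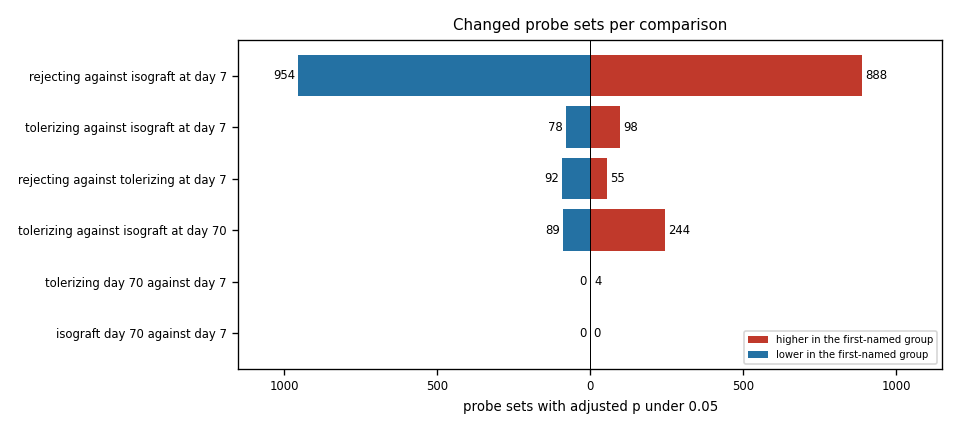
Probe sets with an adjusted p under 0.05 in each comparison (horizontal axis, number of probe sets), with those higher in the first-named group to the right of 0 and those lower to the left. Rejecting allografts against isografts at day 7 gave 888 higher and 954 lower, and isografts at day 70 against day 7 gave 0 in either direction.

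Genes of leukocytes and inflammation rose in rejecting allografts. Arg1 was 24.1-fold higher (log2 difference 4.59, SE 0.87, adjusted p = 0.003056), with a signal of 2359 ± 1818 (SD, n = 3) against 72.4 ± 40.1 (n = 3). Its 3 rejecting arrays gave 3792, 2972 and 314.1, the lowest in the first submission run. Cxcl9 rose 13.6-fold (log2 3.77, SE 0.48, adjusted p = 0.000301) and the integrin gene Itgb2 rose 10.3-fold (log2 3.36, SE 0.33, adjusted p = 5.303e-05). Il1b rose 9.85-fold and Acod1 9.87-fold, with adjusted p of 0.001794 and 0.001127. Gbp2b was at the floor in all 3 isografts and was at least 139.6-fold higher (adjusted p = 1.354e-09). Over both days it read 0.9 to 1.3 in isografts and 807.7 to 2275 in allografts, rejecting or tolerizing. For Gbp2b, donor strain cannot be separated from inflammation. Plaur was at least 13.6-fold higher (adjusted p = 0.0001158). Among T cell and cytotoxic genes, Ccl5 rose 28.9-fold, Cst7 15.7-fold and Cd8a 15.6-fold, while Cd6 was 4.56-fold lower (adjusted p = 0.0008151). The cell division gene Aurkb rose 8.38-fold (adjusted p = 0.0008452).

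The gene lists fixed in advance gave the same picture by count. In the macrophage and monocyte list, 29 of 36 genes were higher and 1 lower (30 and 1 adjusted over the list alone), with a median log2 difference of 1.55 (camera adjusted p = 4.126e-16, adjusted p = 0.1419 with an estimated correlation). The cell cycle list had 26 of 41 genes higher and 0 lower (34 higher adjusted over the list alone, median 1.31, camera adjusted p = 9.143e-16, adjusted p = 0.1419 with an estimated correlation). The interferon-induced list had 18 of 36 higher (18 adjusted over the list alone, median 1.03, camera adjusted p = 8.621e-10, adjusted p = 0.1684 with an estimated correlation). For MHC class I presentation 11 of 14 genes were higher, for class II 10 of 13, for cytotoxic effectors and NK cells 12 of 17, and for T cells 10 of 18 with 1 lower. Adjusted over the list alone these were 12, 10, 13, and 14 with 1 lower. Their camera adjusted p-values were 2.298e-09, 5.379e-08, 1.126e-07 and 5.253e-06, against 0.1419, 0.1419, 0.1419 and 0.2065 with an estimated correlation. Across all 7 contrasts, 91 of the 203 list tests passed with camera's preset correlation and 0 of them with an estimated one.

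Many genes of heart muscle, fatty acid oxidation and the respiratory chain, and some endothelial genes, fell in rejecting allografts. All arrays have nearly the same trimmed mean, and leukocyte lists rose in these hearts. Whether the falls go beyond dilution by leukocyte RNA was not tested against isografts. Idh2 was 16.0-fold lower (log2 -4.00, SE 0.40, adjusted p = 5.303e-05) and Cox7a1 18.4-fold lower (log2 -4.20, SE 0.74, adjusted p = 0.001864). The myosin gene Myh6 was 15.9-fold lower (log2 -3.99, SE 0.88, adjusted p = 0.006722), at 108.7 and 76.3 in the 2 rejecting arrays of the second run and 2212 in the 1 of the first, against 4240 ± 726 (SD, n = 3) in isografts. In a fit of these 2 groups alone the adjusted p of Myh6 was 0.09012. In the list of the tricarboxylic acid cycle and respiratory chain 50 of 65 genes were lower and 0 higher (55 lower adjusted over the list alone, median -1.37, camera adjusted p = 3.815e-19, adjusted p = 0.1662 with an estimated correlation). Its mean in single rejecting arrays, relative to isografts at day 7, ran from -1.69 to -0.74. For fatty acid oxidation 23 of 29 were lower (25 adjusted over the list alone, median -1.88, camera adjusted p = 1.27e-15, adjusted p = 0.1419 with an estimated correlation). For cardiac sarcomere and calcium handling 24 of 32 were lower (25 lower and 1 higher adjusted over the list alone, median -1.75, camera adjusted p = 5.899e-13, adjusted p = 0.1419 with an estimated correlation), and the median was -0.75 in the first run and -2.24 in the second. Endothelial genes had 10 of 21 lower and 1 higher by either count (median -0.95, camera adjusted p = 6.81e-06, adjusted p = 0.1419 with an estimated correlation), and the list means differed by -0.88 with a 95% interval of -1.22 to -0.54. Glycolysis and glucose uptake split, with 5 of 19 genes higher, Pgam1 4.28-fold among them, and 5 lower, Pfkm 7.49-fold among them (7 and 6 adjusted over the list alone, camera adjusted p = 0.8188).

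Some matrix genes were lower in rejecting allografts. Lum was 6.83-fold lower (log2 -2.77, SE 0.19, adjusted p = 7.237e-06), Eln 11.6-fold lower (adjusted p = 2.886e-05) and Postn 11.7-fold lower (adjusted p = 0.0008756). In the matrix and fibrosis list 13 of 50 genes were lower and 3 higher, both over all probe sets and adjusted over the list alone (median -0.46, camera adjusted p = 0.001401, adjusted p = 0.5023 with an estimated correlation). The list means differed by -0.50 with a 95% interval of -1.15 to 0.14. The list's median was -1.79 in the first run and -0.09 in the second, and without rejecting array 3 the median was -0.15 (camera adjusted p = 0.1303).

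The comparison of tolerizing allografts with isografts at day 7 asks what an allograft expresses under costimulation blockade, again with donor strain as part of the difference. It gave 176 changed probe sets, 98 higher and 78 lower. The count was 218 with the run as a block, 40 in the second run alone and 69 in a fit of these 2 groups alone. With the beta-actin ratio as a covariate it was 8. The ratios of these 2 groups do not overlap, so RNA quality and group are poorly separated in this comparison. It was 79 without tolerizing array 3, 76 without tolerizing array 1, 98 without isograft array 1 and 86 without isograft array 2. The sign was the same in the first run for all 176, which is again partly circular. Cxcl9 rose 13.7-fold (log2 3.78, SE 0.48, adjusted p = 0.001311), to 1055 ± 171 (SD, n = 3) from 91.4 ± 69.8 (n = 3). Igtp rose 11.2-fold (log2 3.49, SE 0.32, adjusted p = 0.000101), Irgm1 7.23-fold (adjusted p = 0.003351) and the proteasome gene Psmb9 6.42-fold (adjusted p = 0.0005878). Gbp2b was at least 119.9-fold higher (adjusted p = 2.047e-09). Cst7 rose 8.11-fold (adjusted p = 0.001316) and Cd6 was 3.78-fold lower (adjusted p = 0.008276). Hadh was 4.50-fold lower (log2 -2.17, SE 0.34, adjusted p = 0.004215), Pcp4l1 6.49-fold lower and Fmo1 4.52-fold lower, with adjusted p of 0.006084 and 0.002254. In the second run alone Irgm1, Hadh, Pcp4l1, Fmo1, Cst7 and Cd6 kept their direction, with adjusted p of 0.06149, 0.1651, 0.05813, 0.1161, 0.05289 and 0.1593. In a fit of the 2 groups alone the adjusted p was 0.05057 for Cxcl9 and 0.07767 for Cd6. With the floor at the 50th percentile the call of Cst7 was lost (log2 1.13, adjusted p = 0.1465). With the beta-actin ratio as a covariate Cxcl9 (log2 3.36), Irgm1 (2.22), Psmb9 (2.43), Cst7 (2.67), Cd6 (-2.03), Hadh (-2.28), Pcp4l1 (-2.83) and Fmo1 (-2.05) kept their direction but lost their calls (adjusted p from 0.08183 to 0.2699), and Igtp and Gbp2b kept theirs.

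In the interferon-induced list 14 of 36 genes were higher in tolerizing allografts at day 7 and 0 lower (19 adjusted over the list alone, median 1.16, camera adjusted p = 7.41e-23, adjusted p = 0.06251 with an estimated correlation). MHC class I presentation had 9 of 14 higher (12 adjusted over the list alone, camera adjusted p = 2.531e-17, adjusted p = 0.06251 with an estimated correlation), and class II 8 of 13 (10 adjusted over the list alone, camera adjusted p = 6.162e-15, adjusted p = 0.06251 with an estimated correlation). Fatty acid oxidation had 7 of 29 lower (25 adjusted over the list alone, median -1.22, camera adjusted p = 1.005e-18, adjusted p = 0.06251 with an estimated correlation). Macrophage and monocyte genes had 2 of 36 higher (15 adjusted over the list alone, median 0.91, camera adjusted p = 5.687e-15, adjusted p = 0.1856 with an estimated correlation). The cell cycle list had 0 of 41 called by limma over all probe sets and 14 higher adjusted over the list alone (median 0.70, camera adjusted p = 4.07e-12, adjusted p = 0.2101 with an estimated correlation). The matrix list had 0 of 50 called by either count and a median of 0.03 (camera adjusted p = 0.9551).

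The calls of rejecting and tolerizing allografts against the same isografts overlapped at day 7. There were 93 probe sets higher in both and 68 lower in both, against 8.37 and 7.16 for independent lists, and 0 went opposite ways. The correlation of the log2 differences across probe sets, which are not independent replicates, was 0.746, against a median of 0.501 in 50 simulations of unchanged groups with shared isografts. Their covariance was 0.328 against 0.0706 simulated, a difference of 0.257. The 3 isografts are too few to split, so part of the excess over independent lists may come from the shared controls. The difference in donor strain is common to both comparisons too.

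**Figure D2:**
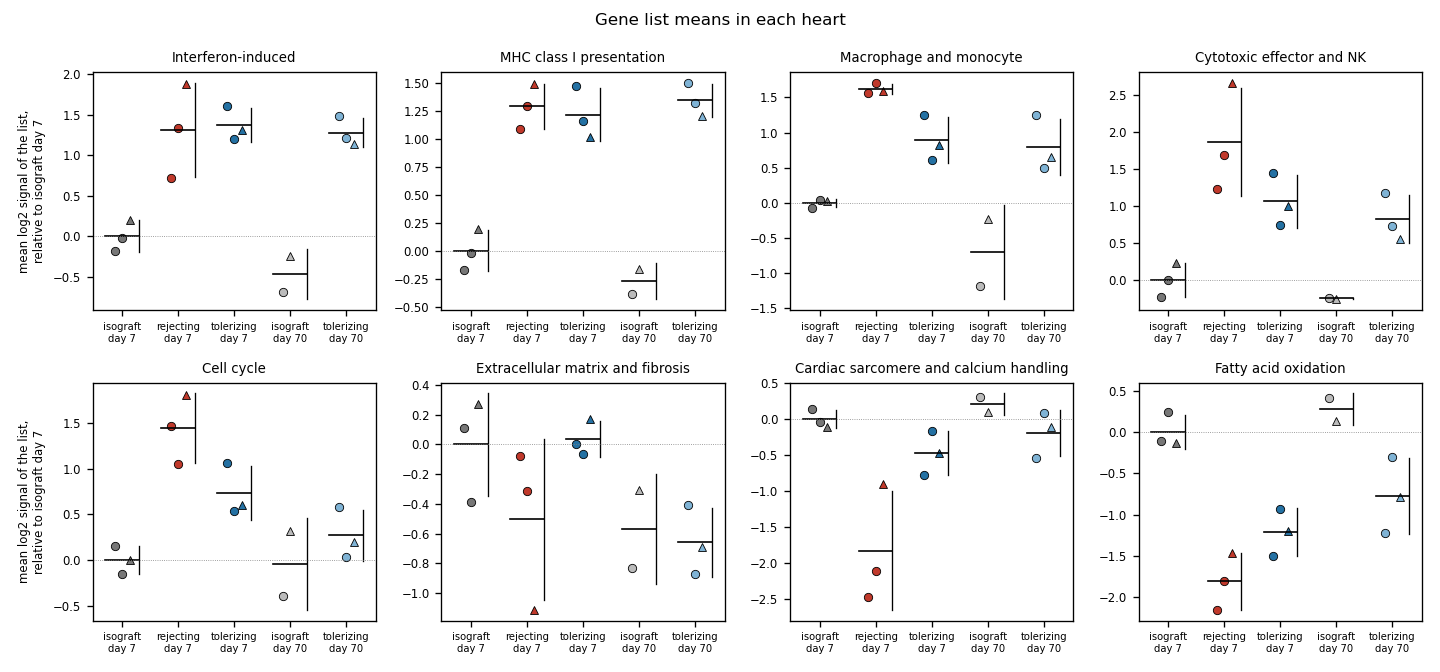
Mean log2 signal of 8 gene lists in each heart, relative to the isografts at day 7 (vertical axis), by group (horizontal axis). Each point is 1 heart, with triangles for the first submission run and circles for the second, horizontal bars for group means and vertical bars for 1 SD. In the cardiac sarcomere panel the rejecting heart of the first run lies apart from those of the second run, and the median difference from isografts is -0.75 in the first run and -2.24 in the second.

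Rejecting against tolerizing allografts at day 7 compares hearts of 1 donor strain with and without costimulation blockade, so strain does not differ. It gave 147 changed probe sets, 55 higher and 92 lower in rejection. The count was 200 with the run as a block, 211 in the second run alone and 43 with the beta-actin ratio as a covariate. The sign was the same in the first run for all 147, which is again partly circular. The count depended on single arrays. It was 771 without rejecting array 3, 73 without rejecting array 1, 50 without rejecting array 2, 58 without tolerizing array 3 and 36 without tolerizing array 2. A fit of these 2 groups alone, without the spread of the other 3, called 20.

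Some single matrix genes were lower in rejecting than tolerizing allografts. Lum was 6.42-fold lower in rejection (log2 -2.68, SE 0.19, adjusted p = 2.198e-05), at 133.8, 206.2 and 166.4 in rejecting allografts against 1075 ± 164 (SD, n = 3) in tolerizing ones. Sparcl1 was 9.62-fold lower (log2 -3.27, SE 0.26, adjusted p = 4.35e-05), Eln 7.18-fold lower (log2 -2.84, SE 0.31, adjusted p = 0.000654) and Postn 12.2-fold lower (log2 -3.61, SE 0.54, adjusted p = 0.005778). Col8a1 was 7.15-fold and Dcn 3.35-fold lower (adjusted p = 0.007108 and 0.005778), and Frzb, at the floor in all 3 rejecting allografts, was at least 9.20-fold lower (adjusted p = 0.00443, 0.05906 in the second run alone). None of these 7 calls was lost on leaving out 1 array of the groups compared, but the fit of these 2 groups alone left Postn, Col8a1 and Dcn at adjusted p of 0.1256, 0.1089 and 0.1455. The matrix and fibrosis list as a whole had 6 of 50 genes lower and 1 higher (12 and 1 adjusted over the list alone, median -0.59, camera adjusted p = 3.533e-06, adjusted p = 0.3365 with an estimated correlation). The list means differed by -0.54 with a 95% interval of -1.18 to 0.11, and the median was -1.44 in the first run and -0.08 in the second. Without rejecting array 3 the median was -0.15 (camera adjusted p = 0.122), so the shift of the whole list rests on that array. The endothelial list had 1 of 21 genes lower and 1 higher (4 and 1 adjusted over the list alone, median -0.43, camera adjusted p = 0.0001847, adjusted p = 0.3365 with an estimated correlation).

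Arg1 was 23.6-fold higher in rejecting than tolerizing allografts (log2 4.56, SE 0.87, adjusted p = 0.02201). The call of Arg1 was lost without tolerizing array 3, rejecting array 1, rejecting array 2 or tolerizing array 2 (adjusted p = 0.05138, 0.1078, 0.1038 and 0.1267). Clec4d was 13.5-fold higher (adjusted p = 0.01635), and its call was lost without rejecting array 1, rejecting array 2 or tolerizing array 2 (adjusted p = 0.05153, 0.07687 and 0.08887). Procr was 5.20-fold higher (adjusted p = 0.007108, 0.05422 without tolerizing array 2). Spint1, at the floor in all 3 tolerizing allografts, was at least 4.18-fold higher (log2 2.06, SE 0.19, adjusted p = 0.0001469). H2-Ea was 5.74-fold lower in rejection (log2 -2.52, SE 0.43, adjusted p = 0.01265), and its call was lost without tolerizing array 3, rejecting array 2 or tolerizing array 2 (adjusted p = 0.05843, 0.06462 and 0.06126). In a fit of these 2 groups alone the adjusted p was 0.212 for Arg1, 0.236 for Clec4d, 0.1089 for Procr and 0.2215 for H2-Ea. With no filter it was 0.08871 for Arg1, 0.0641 for Clec4d and 0.05477 for H2-Ea, and with the floor at the 10th percentile 0.07029 for Arg1. With the beta-actin ratio as a covariate it was 0.06328 for Arg1, 0.06726 for Clec4d and 0.06016 for H2-Ea.

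**Figure D3:**
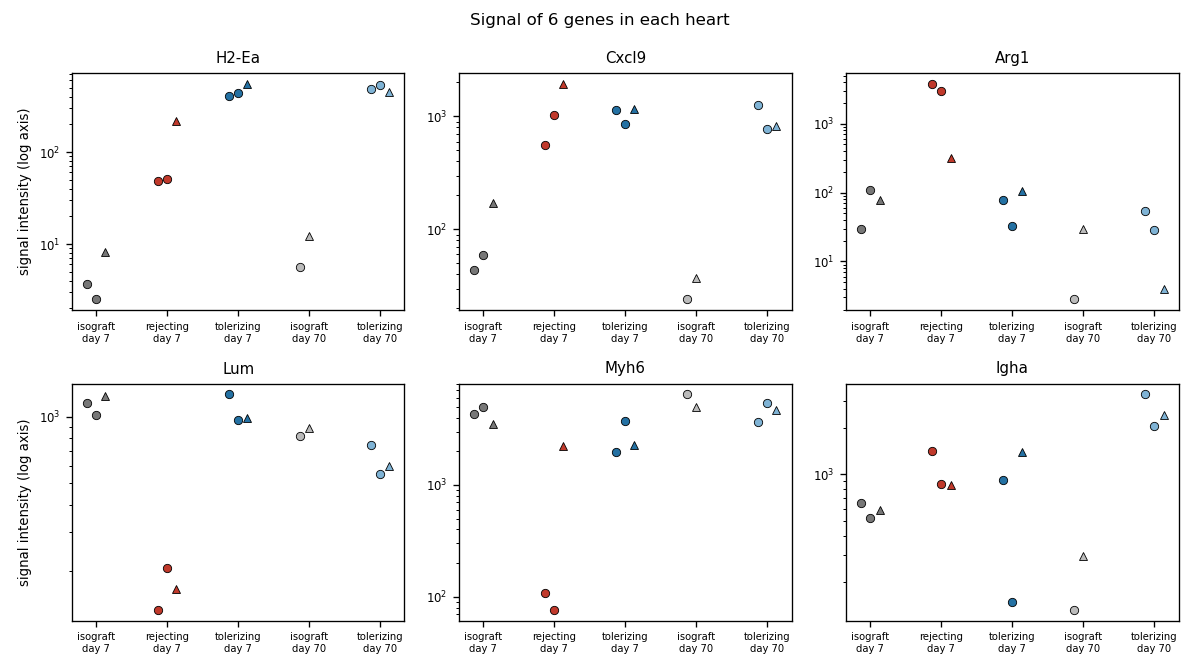
Signal intensity (vertical axis, log scale) of H2-Ea, Cxcl9, Arg1, Lum, Myh6 and Igha in each heart, by group (horizontal axis). Each point is 1 heart, with triangles for the first submission run and circles for the second. The 3 rejecting hearts lie at 133.8, 206.2 and 166.4 for Lum, and at 108.7, 76.3 and 2212 for Myh6.

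Heart muscle lists were lower in rejecting than tolerizing allografts, to a different degree in each run. Cardiac sarcomere and calcium handling had 3 of 32 genes lower (25 lower and 1 higher adjusted over the list alone, median -1.35, camera adjusted p = 3.323e-17, adjusted p = 0.3365 with an estimated correlation), with a median of -0.37 in the first run and -1.67 in the second. The tricarboxylic acid cycle and respiratory chain list had 1 of 65 lower (36 adjusted over the list alone, camera adjusted p = 1.063e-18, adjusted p = 0.3365 with an estimated correlation), with medians of -0.21 and -1.13. The macrophage and monocyte list had 3 of 36 higher (10 adjusted over the list alone, camera adjusted p = 1.833e-09, adjusted p = 0.3365 with an estimated correlation), with medians of 0.91 and 0.58. T cell genes had medians of 2.18 and 0.11, with 1 of 18 higher (1 adjusted over the list alone), and cytotoxic genes 1.86 and 0.27, with 0 of 17 called by limma (4 higher adjusted over the list alone). Their camera adjusted p-values were 0.0009061 and 0.0002827, against 0.3736 and 0.3365 with an estimated correlation. Without rejecting array 3 they were 0.4046 and 0.1407.

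Interferon and antigen presentation lists did not pass the test between rejecting and tolerizing allografts with all arrays. The interferon-induced list had 0 of 36 genes called by limma or adjusted over the list alone, a median of -0.01 and camera adjusted p = 0.6518. The difference of its list means was -0.06 with a 95% interval of -0.67 to 0.56, and its median was 0.46 in the first run and -0.35 in the second. It passed in opposite directions without rejecting array 1 (0.15, adjusted p = 0.04795) and without rejecting array 3 (-0.34, adjusted p = 0.01141). MHC class I presentation had 0 of 14 called by either count (camera adjusted p = 0.6518) and a difference of list means of 0.07 with an interval of -0.28 to 0.42. For class II, H2-Ea was the 1 gene of 13 called by either count, as lower (camera adjusted p = 0.3188), and the list means differed by 0.08 with an interval of -0.51 to 0.67. The fall of H2-Ea is part of that mean. The array medians of 6 other class II genes differed by 0.54 (SE 0.30). The class II list passed without tolerizing array 1 (median 0.50, adjusted p = 0.01906). Ifng was 3.44-fold higher in rejection without passing (log2 1.78, SE 0.46, adjusted p = 0.08028). It passed without rejecting array 3 (log2 1.06, adjusted p = 0.03011), without rejecting array 1 (log2 2.38, adjusted p = 0.01214) and with array weights (log2 1.55, adjusted p = 0.003006).

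Tolerizing allografts against isografts at day 70 asks what marks a long-standing tolerized allograft, with donor strain part of the difference. It gave 333 changed probe sets, 244 higher and 89 lower. The count was 405 with the run as a block, 182 in the second run alone, 37 in a fit of these 2 groups alone, 266 with the beta-actin ratio as a covariate, 82 without isograft array 1 and 144 without tolerizing array 1. The beta-actin ratios of these 2 groups do not overlap either, so RNA quality and group are poorly separated here too. The sign was the same in the first run for all 333, which is again partly circular. Cxcl9 was 31.1-fold higher (log2 4.96, SE 0.54, adjusted p = 0.0001858), at 950 ± 263 (SD, n = 3) against 30.6 ± 9.3 (n = 2). Igtp rose 14.9-fold (adjusted p = 4.885e-05), Ifi47 13.7-fold (adjusted p = 0.0009868), Psmb8 7.03-fold (adjusted p = 9.661e-05) and H2-Ab1 7.59-fold (adjusted p = 0.0003062). Gbp2b was at least 75.1-fold higher (adjusted p = 3.473e-08) and Igkv10-96, an immunoglobulin kappa gene, at least 25.3-fold (adjusted p = 0.0002128). Probe sets of immunoglobulin genes may detect near-identical genes. Igha rose 12.9-fold (adjusted p = 0.008814), C1qb 5.55-fold (adjusted p = 0.002627) and Ccl8 21.6-fold (adjusted p = 0.005608), and Inmt was 17.3-fold lower (adjusted p = 0.005484). Those 4 calls were lost without isograft array 1, with log2 of 3.11, 1.78, 2.67 and -3.72 in place of 3.69, 2.47, 4.44 and -4.11 and adjusted p of 0.1642, 0.05292, 0.06957 and 0.1017. In a fit of the 2 groups alone their adjusted p was 0.06621, 0.1622, 0.2291 and 0.07028, and that of H2-Ab1 and Igkv10-96 was 0.05126. In the second run alone it was 0.07736 for Igha and 0.1196 for Inmt. Leaving out isograft array 1 leaves 1 isograft, which is assumed to vary like the other groups.

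At day 70 the interferon-induced list had 16 of 36 genes higher and 0 lower (27 adjusted over the list alone, median 1.79, camera adjusted p = 7.612e-28, adjusted p = 0.06015 with an estimated correlation). Macrophage and monocyte genes had 19 of 36 higher (26 adjusted over the list alone, median 1.48, camera adjusted p = 9.233e-28, adjusted p = 0.07446 with an estimated correlation). MHC class I presentation had 12 of 14 higher (12 adjusted over the list alone, camera adjusted p = 2.751e-20, adjusted p = 0.05416 with an estimated correlation) and class II 9 of 13 (10 adjusted over the list alone, camera adjusted p = 1.347e-18, adjusted p = 0.06015 with an estimated correlation). Fatty acid oxidation had 4 of 29 lower (13 adjusted over the list alone, median -1.02, camera adjusted p = 8.149e-11, adjusted p = 0.1524 with an estimated correlation). Probe sets called the same way in tolerizing allografts at both days numbered 121, 82 higher and 39 lower, against 2.30 and 0.668 for independent lists. The tolerizing and isograft arrays of the 2 days are separate, so these comparisons share no controls. They do share the estimate of spread per probe set and the difference in donor strain. Either can raise the overlap above that of independent lists.

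Within tolerizing allografts, day 70 against day 7 asks what changes as tolerance is maintained, with no strain difference. It gave 4 changed probe sets, all higher, with 645 at an unadjusted p under 0.05 against 520 from chance. All 4 were of immunoglobulin genes and are named after their values were seen. They are 3 probe sets of Igkv10-96 (log2 3.68, 3.82 and 3.08, adjusted p = 0.009734, 0.009734 and 0.04021) and 1 of Ighm (at least 70.7-fold higher, adjusted p = 0.009734). The count was 3 with the run as a block and 0 in the second run alone, 0 without tolerizing day 7 array 1 or array 2, 1 without day 70 array 1 and 34 without day 70 array 2. A fit of the 2 groups alone called 0, as did one with the beta-actin ratio as a covariate. The brightest probe set of Igkv10-96 lost its call without day 7 array 1 or 2 or day 70 array 1 (adjusted p = 0.05447, 0.07266 and 0.05783), and had an adjusted p of 0.1708 with the floor at the 10th percentile, 0.1625 with no filter, 0.35 in the second run alone, 0.3342 in the fit of the 2 groups alone and 0.183 with the beta-actin ratio. The probe set that stands for Ighm, a brighter one than that named here, was not called (adjusted p = 0.4596). The matrix and fibrosis list had 0 of 50 genes called over all probe sets and 12 lower adjusted over the list alone (median -0.51, camera adjusted p = 1.86e-11, adjusted p = 0.8507 with an estimated correlation), with a median of -0.69 in the first run and -0.50 in the second. Isografts went the same way over this time, with a list mean of -0.57 (95% interval -1.29 to 0.15) against -0.69 (-1.34 to -0.05) in tolerizing allografts. The difference between these was -0.12 with an interval of -1.09 to 0.84, so a fall beyond that in isografts is not shown.

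Isografts at day 70 against day 7 ask what time after surgery changes without an immune mismatch. limma called 0 probe sets, with 559 at an unadjusted p under 0.05 against 520 from chance and a smallest adjusted p of 0.06308. The count was 32 without isograft day 70 array 2, and 1 without isograft day 7 array 3 or array 2. The macrophage and monocyte list had 0 of 36 genes called over all probe sets and 9 lower adjusted over the list alone (median -0.81, camera adjusted p = 3.52e-15, adjusted p = 0.5379 with an estimated correlation), with a median of -0.34 in the first run and -1.20 in the second. Complement genes had 4 of 13 lower adjusted over the list alone and 0 over all probe sets (median -0.63, camera adjusted p = 2.119e-07, adjusted p = 0.5379 with an estimated correlation). For the interaction, whether the difference between tolerizing allografts and isografts changes from day 7 to day 70, limma called 0 probe sets. There were 409 at an unadjusted p under 0.05 against 520 from chance, and the smallest adjusted p was 0.1845. So a gene called at 1 day and not at the other is not shown to differ between days.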

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

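The list tests below were planned. The tests of explanations were chosen after the patterns were seen and before their own values were computed, except that H2-Eb1, 1 of 6 class II genes, had been looked at. The condition added to the dilution test of matrix genes, the second reading of 3 tests, the standard errors from the arrays compared alone and the values of endothelial genes were chosen after the result was seen. Some lists stood out because the difference between tolerizing allografts and isografts was not the same at day 70 as at day 7, by camera on the interaction itself. The median log2 change of that difference was 0.70 for macrophage and monocyte genes (adjusted p = 2.054e-10), 0.58 for complement (adjusted p = 1.15e-07), 0.85 for MHC class II presentation (adjusted p = 0.0001065), 0.54 for MHC class I presentation (adjusted p = 9.999e-05), 0.45 for interferon-induced genes (adjusted p = 0.0001065), 0.17 for B cell and plasma cell genes (adjusted p = 0.0002314) and -0.47 for cell cycle genes (adjusted p = 0.0004674). With an estimated correlation none of these 7 held, with adjusted p of 0.5933, 0.4835, 0.5933, 0.5933, 0.8396, 0.5933 and 0.8396 in that order, and fry gave 0 of 29 lists. List means were also set relative to isografts at day 7. In the 2 isografts at day 70 they were -0.70 for macrophage, -0.65 for complement and -0.47 for interferon-induced genes. In tolerizing hearts they went from 0.89 to 0.80, 0.27 to 0.35 and 1.37 to 1.28. Those shifts thus lay mostly in isografts. Class I and II means moved in both kinds of heart. B cell (-0.01 to 0.73) and cell cycle (0.73 to 0.27) means moved mostly in tolerizing hearts. Without isograft day 70 array 1, 4 lists passed, and the medians were 0.18 for macrophage and monocyte (adjusted p = 0.09981), 0.39 for class II (adjusted p = 0.07383) and 0.23 for interferon-induced genes (adjusted p = 0.2753). The cell cycle list did not pass without isograft day 70 array 2 (-0.09, adjusted p = 0.9338) or tolerizing day 7 array 1 (-0.29, adjusted p = 0.07035). Among medians that kept their call, macrophage genes moved to 1.11 and interferon-induced genes to 0.74 without isograft day 70 array 2, and macrophage genes to 0.45 without tolerizing day 70 array 1. The B cell and plasma cell median moved by over 1.5 times without each array of the 4 groups except tolerizing day 7 arrays 2 and 3. It was 0.34 and 0.10 without isograft day 7 arrays 1 and 2, 0.34 without array 3, 0.35 and 0.11 without isograft day 70 arrays 1 and 2, 0.65 without tolerizing day 7 array 1, and 0.08, 0.44 and 0.33 without tolerizing day 70 arrays 1, 2 and 3. limma called 0 single probe sets, with 409 at an unadjusted p under 0.05, fewer than the 520 from chance.

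Of 50 matrix genes, 6 were lower and 1 higher in rejecting than in tolerizing allografts at day 7, with a list mean of -0.54 (95% interval -1.18 to 0.11), an adjusted p of 0.3365 with an estimated correlation, and a median of -0.15 (camera adjusted p = 0.122) without rejecting array 3. Dilution by RNA of infiltrating leukocytes predicts that matrix and heart muscle lists fall alike. The matrix list mean minus the cardiac list mean differed by 0.82 (SE 0.62, or 0.82 from the arrays compared alone), and as 2 standard errors, at least 1.24, exceed the matrix shift itself, dilution cannot be told apart from a separate fall of matrix genes; endothelial genes, also resident, differed by -0.43, and matrix minus endothelial genes by -0.11 (SE 0.29, or 0.34) and cardiac minus endothelial genes by -0.93 (SE 0.37, or 0.49), both within 2 of the larger standard errors. A constant offset between submission runs cancels, since each of these groups has 1 array of the first and 2 of the second, and the list mean was -0.54 with or without the run as a block. A run difference that is unequal between the groups cannot be told apart from rejection itself, as the median was -1.44 in the first run and -0.084 in the second and the blocked mean lies within 2 standard errors (SE 0.30) of 0. A response of the tissue to rejection, the difference the design names, stays open and untested.

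H2-Ea was lower in rejecting than in tolerizing allografts, by a log2 of -2.52 (SE 0.49 from the spread of all 14 arrays, 0.73 from these 6 alone). Dilution of donor RNA by recipient leukocyte RNA predicts an equal fall of donor heart muscle genes, but the cardiac list lay 1.14 above H2-Ea (SE 0.27, or 0.30 from these 6 arrays), or 1.17 as a median of gene differences, and endothelial genes 2.09 above it (SE 0.48, or 0.70), which argues against dilution as the whole cause. A general fall of class II genes predicts the same fall in 6 others, but their median lay 3.07 above H2-Ea (SE 0.62, or 0.89 from these 6 arrays), or 2.91 by the other reading. This speaks only to class II RNA of the whole graft. Recipients are C57BL/6, so H2-Ea comes from donor cells alone, while the 6 others may also come from recipient leukocytes. A fall of class II genes in donor cells thus stays open. Rejection itself, the difference the design names, stays open and untested, and limma's call of H2-Ea was lost without tolerizing array 3, rejecting array 2 or tolerizing array 2 (adjusted p = 0.05843, 0.06462 and 0.06126).

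Immunoglobulin probe sets were higher in tolerizing allografts at day 70 than at day 7, with 47 of 52 positive, 4 called and a median log2 difference of 2.05, against -0.24 in isografts over the same time. One array with a very high signal predicts that the mean difference of 1.85 drops by more than 50% without it, but it was 1.69, 1.56 and 2.31 without day 70 arrays 3, 1 and 2, which argues against that. Lymphoid tissue on the graft predicts a rise of at least 1 in B cell surface and lymph node genes, of which 9 were measured: the difference of array medians was 0.40 (SE 0.32, or 0.21 from the arrays compared alone) and the median of gene differences 0.07. Both lie under 1 by more than 2 of the smaller standard errors but the first does not by 2 of the larger, so this cannot be told apart from a rise of antibody-secreting cells. On the interaction limma called 0 of the 52 probe sets singly, 49 were positive and their mean was 2.24 (SE 0.69, or 0.55; 1.95 to 2.70 without 1 array), over 2 standard errors above an equal change in isografts, but this is an estimate and no separate test, as the class was chosen for a rise that is part of the interaction.

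The counts were set against the other splits of the same 6 arrays into groups of 3. The real split gave 1842 probe sets for rejecting against isograft hearts, where the highest other split gave 3. For tolerizing against isograft hearts at day 7 it gave 176 against 2, for rejecting against tolerizing hearts 147 against 9, and for tolerizing hearts over time 4 against 1. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The other splits also mix the groups, so a real difference enters their spread and lowers their counts. Their low counts are no measure of chance.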

How the results depend on the processing

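The second run alone, the beta-actin ratio as a covariate, and the run block for lists and overlap, were chosen after seeing the data. The cause of a moved count was not tested, except that fewer samples or more probe sets tested follow from an alternative's construction. Comparisons follow the order rejecting against isograft, tolerizing against isograft, rejecting against tolerizing (all at day 7), tolerizing against isograft at day 70, tolerizing over time, isografts over time and the interaction. Counts moved by over 1.5 times as follows. Array weights, whose estimation stopped before convergence, gave 2948, 364 and 1512 in the first 3 and 46 for tolerizing over time. A fit of only the groups compared gave 1153, 69, 20, 37 and 0 in the first 5. With no filter they were 103 in the second, 63 in the third, 0 in the fifth, 9 in the sixth and 3 for the interaction. A floor at the 50th percentile gave 235 in the third and 2 for the interaction, and at the 10th 0 in the fifth. The second run alone gave 40 in the second, 182 in the fourth and 0 in the fifth. The beta-actin ratio as a covariate gave 8 in the second, 43 in the third and 0 in the fifth. That ratio goes with the groups, so this fit separates RNA quality from group poorly.

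Leaving out 1 array gave 1307 to 2168, 76 to 136, 36 to 771, 82 to 337, 0 to 34, 0 to 32 and 0 to 2. The extremes outside 1.5 times came without tolerizing day 7 array 1 (76), tolerizing day 7 array 2 (36), rejecting array 3 (771), isograft day 70 array 1 (82), tolerizing day 70 array 2 (34 and 2) and isograft day 70 array 2 (32). Other scalings, no intensity trend, the pseudocount, the stricter filter, the 2-fold minimum and the run as a block moved no count by over 1.5 times. Further arrays are named in the results above. The overlap of 161 was 150 to 194 under its 5 alternatives.

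Whether replicate numbers pair the arrays is not stated: same-numbered arrays of different groups correlated at -0.18 to 0.34 over 26 pairs, 11 of them over 0.1, and 9 of 14 arrays matched their own number best, a hint from the data only. The replicate block gave 12 for tolerizing over time and moved no other count by over 1.5 times.

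Lists past the threshold numbered 20, 15, 15, 16, 9, 9 and 7. An estimated correlation gave 0 in all 7, and fry gave 17, 9, 0, 8, 0, 0 and 0. Leaving out 1 array gave 18 to 20, 13 to 17, 11 to 15, 14 to 17, 6 to 10, 5 to 11 and 4 to 9. Of 556 such refits of called lists, 63 lost the call. Some lists were called in opposite directions depending on the array left out: interferon-induced genes in rejecting against tolerizing without rejecting array 1 (0.15) or 3 (-0.34), and cell cycle genes in isografts over time without day 70 array 1 (0.22) or 2 (-0.44), with adjusted p of 0.04795, 0.01141, 0.006442 and 0.0009794. The respiratory chain list in the interaction passed only without tolerizing day 70 array 1 (0.20, adjusted p = 0.03178), and ranged down to -0.14 without tolerizing day 7 array 1 (adjusted p = 0.163). With all arrays none of these 3 passed, with adjusted p of 0.6518, 0.7303 and 0.9998.

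Of 54 called gene differences printed, none reversed under the alternatives. Calls were lost in 18 of 313 refits without 1 array, and of the 54, 17 in the fit of only the groups compared, 10 in the second run alone, 12 with the beta-actin ratio as a covariate, 4 with no filter and 2 with the floor at the 10th percentile. With the floor at the 50th it was 1 of 53. Of all 218 called genes the naming rule gives, 84 lost the call without at least 1 of the arrays, against 8 of the 53 of them printed, so those printed are steadier than the rest. Igkv10-96 in tolerizing hearts over time, printed outside the rule, lost it too. For rejecting against tolerizing hearts it was 25 of 33, and for tolerizing against isograft hearts at day 70 it was 33 of 51. Signals near the floor limit small differences: 71.97% to 78.8% of probe sets lay above it.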

Other observations

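Probe sets called the same way in all 3 comparisons of allografts with isografts numbered 116, 81 higher and 35 lower. The calls of rejecting and tolerizing hearts at day 7 among them share the same isografts. Gbp2b read 0.9 to 1.3 in the isografts and 807.7 to 2275 in the allografts. Pdxdc1 had 1 probe set at 6.2 to 15.2 in isografts and 67.1 to 374 in allografts. Its other 2 read 136.5 to 170.2 and 77.6 to 123 in isografts, against 11.2 to 89.3 and 19.2 to 76.9 in allografts. Neither of those was called lower in rejecting hearts against isografts. Gbp2b and Pdxdc1 were singled out after their values were seen.

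In rejecting hearts against isografts at day 7, 3 of 9 adipocyte genes were lower, beside 954 of 10395 probe sets called lower over the whole array. These 2 shares were not compared by a test. The adipocyte list passed camera (median -0.74, adjusted p = 0.03139, 0.1761 with an estimated correlation), but not without rejecting array 3 (adjusted p = 0.08049) or isograft array 2 (adjusted p = 0.1194). Of other tissue lists, limma called 0 of 6 erythroid, 0 of 7 lymph node and thymus and 0 of 11 skeletal muscle genes. It called 1 of 7 smooth muscle genes lower and 2 of 8 platelet and mast cell genes higher. Over the whole array it called 888 of 10395 probe sets higher and 954 lower. Neutrophil genes had 2 of 12 higher (camera adjusted p = 0.0491, adjusted p = 0.5023 with an estimated correlation). That list did not pass with quantile scaling (adjusted p = 0.0513), the replicate block (adjusted p = 0.06123) or the run as a block (adjusted p = 0.06596). Its median of 0.57 was 0.07 without rejecting array 1 (adjusted p = 0.4223) and 0.45 without isograft array 3 (adjusted p = 0.1476). Between rejecting and tolerizing hearts the median was -0.29 in the first run and 1.06 in the second.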
